A study of Homo sapiens with 6 samples.

How the data were processed

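RNA was measured in 6 libraries of K562 cells, 3 given 0.1% DMSO and 3 given 10 µM HR-19011 for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, its integrity was checked, and stranded libraries were made from polyadenylated RNA. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, HISAT, Bowtie2, SAMtools 1.9, StringTie 2.1.3b and DESeq2 1.24.0, and the GRCh38 build, without saying what each did. The deposited values, per the file headers, are FPKM per gene, normalized by the authors to transcript length and library size, for 46427 genes with NCBI gene identifiers. How reads that match several genes were divided is not given in the sources used here, so near-identical copies (alpha and gamma globin pairs, HSPA1A and HSPA1B, histones, SPRR2D, AKR1C1, and ferritin and ribosomal protein genes with processed pseudogenes) are uncertain, and so are small nucleolar RNA genes inside introns of hosts. Such values cannot tell a small group of reads from none, and a listed 0 can be a failed estimate, so genes are only said to be listed at 0.

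Depth is unknown. Low values were searched for whole multiples of what 1 read would give, in single-transcript genes up to 1500 bases long. At the best of many candidate steps, 25.2% to 31.9% of values per library lay within 0.1 of a whole multiple. Chance gives 20% for 1 fixed step and more for the best of many. Lengths were gene spans, so genes with introns could not show whole multiples. Reads were therefore not recovered, and no counting interval or count model was used. No pair of libraries was a duplicate: at most 0.084% of values were identical within a group.

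Groups came from the sample titles. The design, gene lists, named genes and alternatives were fixed before the data were examined, except where an alternative is said to have been added. Genes with a mean of at least 1 FPKM over the 6 libraries (11856) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term, a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment over all tested genes, at a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes; folds given without log2 are ratios of group mean FPKM. An exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.1 and was not used. A 2-fold change means an absolute log2 fold change of at least 1 beside the threshold, and is not a test against 2-fold.

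The 34 gene lists were tested with camera in limma, two-sided, with its preset correlation of 0.01 and with adjustment over lists, where at least 3 members were measured (33 lists). Camera with an estimated correlation and fry were the alternatives. Counts adjusted over the list alone repeat the adjustment within each list. The 13 mitochondrially encoded subunits carry names without the MT prefix in the files and were matched by hand.

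The genes named are the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 FPKM and no overlap between groups, 15 genes fixed by name, and up to 4 members of each list with the smallest p, at least 1 per direction where both were called. These came to 154 genes, of which some, with 1 of the gene lists, are not reported here. Gene positions are from the RefSeq table of the GRCh38 assembly by NCBI gene identifier. FGF21, HMOX1, IFIT1 and MX1, list members below the filter, and the genes named from families picked by symbol were chosen after their values were seen.

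The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, TMM scaling (trimming 30% of log ratios and 5% of mean logs, written for this purpose), TPM, quantile normalization, equal totals without globin and mitochondrial genes, no variance trend, the replicate number as a block, each library left out, protein-coding genes alone, a threshold of 0.01, and a test against 1.5-fold. Equal totals without the 100 highest genes, leaving out small nucleolar RNA genes, and gene families picked by symbol prefix were added after seeing the data. Small nucleolar RNA genes were assigned the most abundant tested gene that contains them on the same strand, from GENCODE annotation on GRCh38, for 167 of 176, of which 20 lacked a strand in that annotation. A first match by symbol alone covered too few of them, so positions by gene identifier and newer symbols were added after its result was seen. Intervals for their medians come from resampling hosts, a unit the prediction written beforehand did not name.

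The test was tried on simulated values with the spread of these genes, 11856 genes in 3 against 3 libraries. It recovered 68% of 50 genes changed 1.25-fold, 96% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 9 of 11656 unchanged genes. Most simulated genes were unchanged, and as many were raised as lowered, whereas 84.4% of the real genes were called. The rate of false calls among unchanged genes therefore does not carry over to the real test, where it can be higher. Camera gave a p under 0.05 to 4 of 200 random lists. The simulated genes varied independently of one another. This therefore does not check camera for correlated genes, on which the calls of the real lists depend. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.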

Results

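Polyadenylated RNA was profiled in K562, a human cell line established from a patient with chronic myeloid leukemia that carries the BCR-ABL1 fusion and expresses fetal and embryonic globins. Cells received 10 µM HR-19011, a compound known here by its code name, for 24 h, or 0.1% DMSO as vehicle, and the labels do not state the DMSO percentage of the HR-19011 libraries, so a difference in DMSO is not excluded. Each group had 3 libraries, and the labels do not say whether these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series title names the HRI, eIF2α and ATF4 pathway of the integrated stress response, and the comparison asks how the transcriptome of treated cells differed from that of vehicle cells. The deposited values were FPKM for 46427 genes per library, with no read counts, so the sequencing depth behind each value is unknown. Summed FPKM was 461938 ± 5487 (SD, n = 3) in vehicle and 423885 ± 3632 in HR-19011.

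Transcripts of the mitochondrial genome took 20.6% ± 0.564 (SD, n = 3) of the summed FPKM in vehicle libraries and 14.2% ± 0.221 in HR-19011 libraries, and globin transcripts took 2.58% ± 0.0474 and 1.09% ± 0.0272. Genes listed at 1 FPKM or more numbered 11233 ± 15.0 in vehicle and 12126 ± 6.08 in HR-19011, with no overlap between the groups. Pearson correlation of log2(FPKM + 1) lay between 0.997 and 0.998 within groups and between 0.891 and 0.894 across groups. The first principal component held 96.8% of the variance and separated the treated from the vehicle libraries.

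The 10 highest genes after HR-19011, by the rule fixed beforehand, were led by SPRR2D, a small proline-rich protein of epithelial envelopes with closely similar family members, which went from 1.42 ± 0.360 to 252 ± 2.67 FPKM (SD, n = 3), and the chemokine CXCL8 from 0.742 ± 0.106 to 143 ± 11.3 FPKM. DDIT4, an inhibitor of mTORC1 signalling, rose 33.3-fold, the stress cytokine GDF15 27.1-fold, SH3BGR 29.5-fold, and the collagen chain gene COL6A3 42.0-fold. INHBE, an inhibin beta subunit gene, reached 29.8 FPKM from 0.265, the cytokine receptor subunit gene IL20RB 33.9 from 0.583, KLHDC7B 21.8 from 0.0449, and the uncharacterized locus LOC105370924 21.7 from 0.0540. At the other end, the neurofilament gene NEFH fell 18.5-fold, ARHGAP22 19.3-fold, FAM178B 8.08-fold and POLR1G, a subunit of RNA polymerase I, 9.62-fold. The globin pseudogene HBBP1 went from 43.3 ± 1.05 to 3.61 ± 0.432 FPKM; it lies in a family of similar sequences, and its share of reads is uncertain. The erythroid transcription factor KLF1 fell 6.99-fold, from 79.9 ± 3.56 to 11.4 ± 0.160 FPKM, and the neuropeptide gene NMU and the hematopoietic gene HEMGN fell 6.64-fold and 6.63-fold. IFI30, a lysosomal thiol reductase gene, fell 6.11-fold, and the small nucleolar RNA gene SNORD12C was listed 8.53-fold lower, a value read with the limit given in the next paragraph.

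Of 11856 genes tested, 10009 (84.4%) differed between the groups in the limma test at a Benjamini-Hochberg adjusted p under 0.05, with 5506 higher and 4503 lower in HR-19011. At least 2-fold changes on the log2(FPKM + 1) scale were found for 2192 genes, 1427 higher and 765 lower. Values of the 3 treated and 3 vehicle libraries did not overlap for 85.2% of the tested genes, against 10% by chance. Of 176 small nucleolar RNA genes tested, 149 were listed lower and 6 higher, with a median log2 fold change of -0.99, and without a filter on low values 160 of 329 (48.6%) were lower. Their values come from polyadenylated RNA, and how reads shared with host genes were divided is not given in the sources used here, so they are not taken as levels of the mature RNAs. The 134 other genes spanning under 300 bases had a median of -0.31. The balance of directions depended on the scaling of the libraries: higher genes made up 55.0% of the called genes with FPKM as deposited, 40.7% after TMM scaling, 46.1% after quantile normalization and 62.2% after conversion to TPM. It also depended on the filter, with 64.4% higher without one and 47.5% with a mean of at least 5 FPKM. For 2-fold changes the higher share was 65.1% as deposited, 43.2% after TMM scaling, 53.4% after quantile normalization and 74.2% after conversion to TPM. The median log2 fold change of all tested genes, 0.07 as deposited, shifted by -0.21 under TMM, -0.13 under quantile normalization and 0.12 under conversion to TPM.

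**Figure D1:**
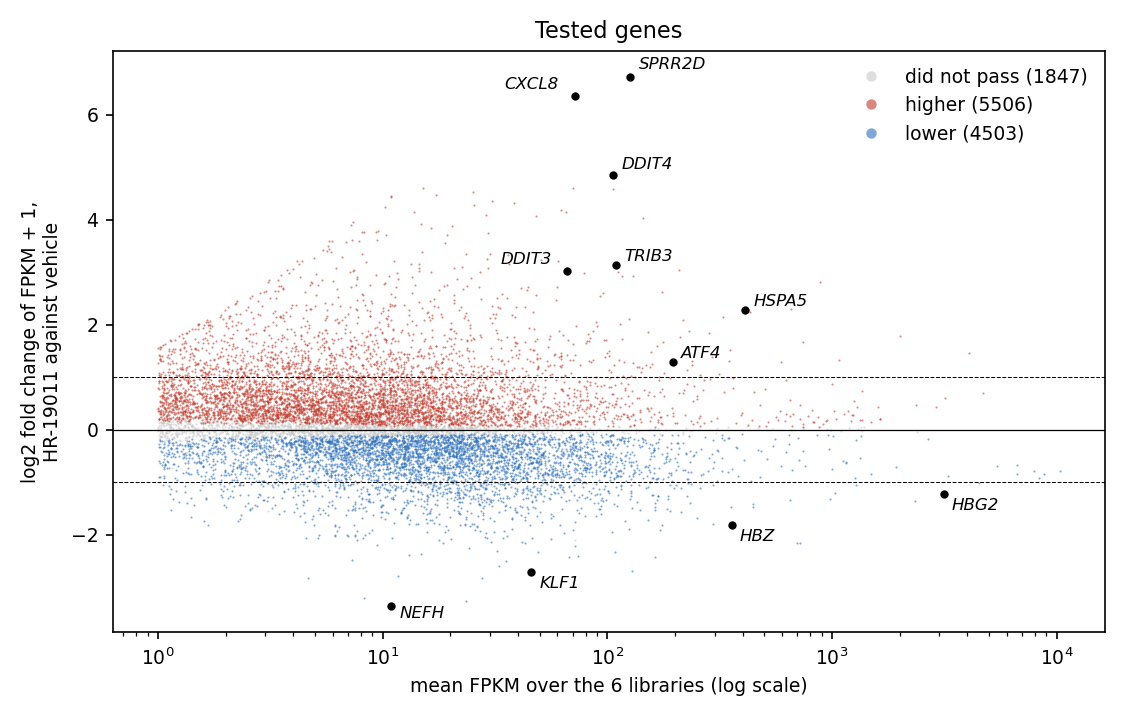
Log2 fold change of FPKM + 1 (HR-19011 against vehicle, vertical axis) against the mean FPKM over the 6 libraries (horizontal log axis) for the 11856 tested genes, colored by direction at an adjusted p under 0.05 in limma. Dashed lines mark 2-fold changes, SPRR2D and CXCL8 lie highest at 6.72 and 6.36, and NEFH lies lowest at -3.35.

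Genes of the integrated stress response rose together. ATF4, its central transcription factor, went from 113 ± 7.51 to 278 ± 47.9 FPKM (SD, n = 3), a log2 fold change of 1.28 (SE 0.105). Its partner and target DDIT3, encoding CHOP, went from 13.6 ± 1.05 to 119 ± 1.12 FPKM, 8.69-fold, and ATF3 from 3.18 ± 0.203 to 55.4 ± 1.51 FPKM, 17.4-fold. The pseudokinase gene TRIB3 rose 9.14-fold, ATF5 7.85-fold, and PPP1R15A, which encodes the stress-induced phosphatase subunit GADD34, 2.73-fold. All 11 measured transcription factors and regulators of the response were higher, over all genes and adjusted over the list alone, with a median log2 fold change of 1.85. In the camera test this list had an adjusted p = 9.86e-05, and adjusted p = 0.153 with an estimated correlation. On GRCh38, ATF4 lies on chromosome 22 from 39520559 to 39522686, DDIT3 on chromosome 12 from 57516588 to 57520517, and ATF3 on chromosome 1 from 212565407 to 212620777.

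All 15 measured effector targets of ATF4 and CHOP rose as well, also when adjusted over the list alone, with a median log2 fold change of 2.34 (camera adjusted p = 3.25e-06, and adjusted p = 0.153 with an estimated correlation). Besides DDIT4, GDF15 and INHBE they included VEGFA, an angiogenic growth factor, at 5.80-fold, and CHAC1, a glutathione-degrading enzyme, which went from 0.435 ± 0.174 to 9.15 ± 1.38 FPKM. FGF21 was listed at 0 in all vehicle libraries and at 0.0659 ± 0.0186 FPKM in HR-19011.

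**Figure D2:**
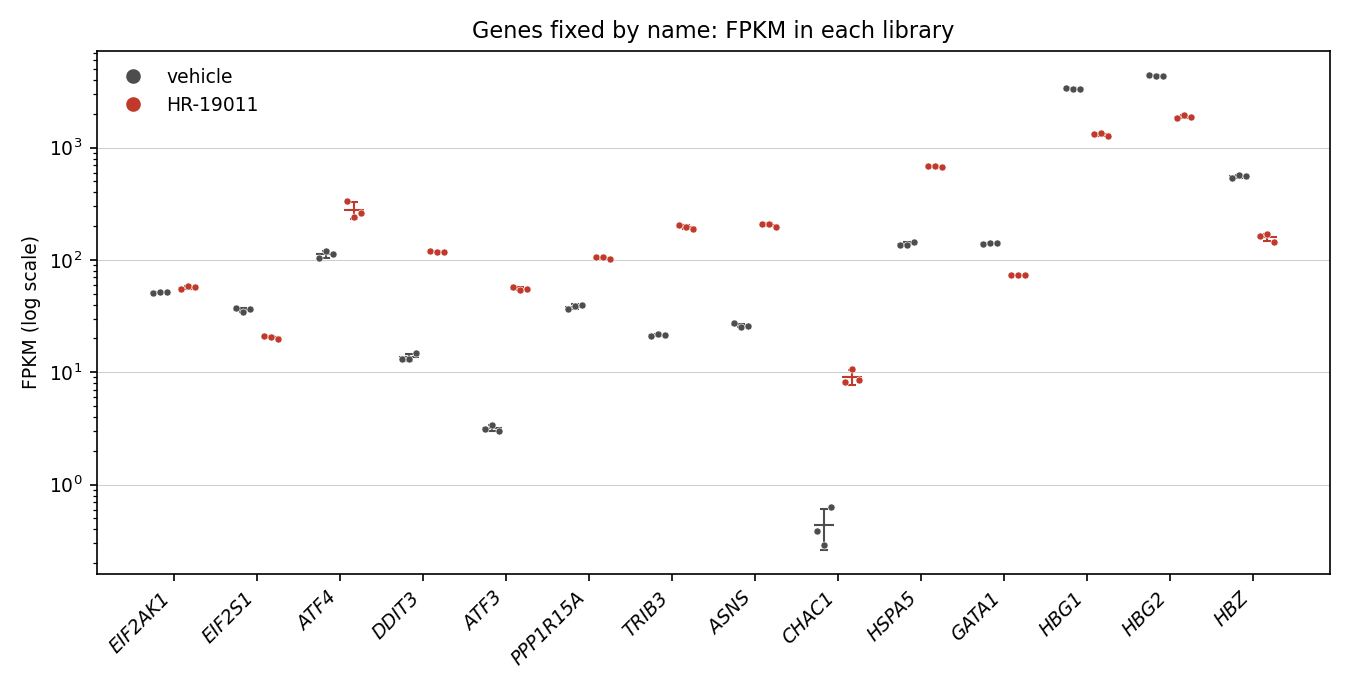
FPKM (vertical log axis) of 14 genes fixed by name, in each of the 3 vehicle and 3 HR-19011 libraries; dots are libraries, horizontal marks are means and bars are SD. DDIT3, ATF3, TRIB3, ASNS and CHAC1 separate the groups most, whereas EIF2AK1 differs by a log2 fold change of 0.13, with the opposite sign (-0.11) after TMM scaling.

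The kinase and substrate named in the title moved little or downward at the RNA level. EIF2AK1, encoding HRI, was listed at 51.6 ± 0.582 FPKM in vehicle and 56.8 ± 1.58 in HR-19011, a log2 fold change of 0.13 (SE 0.0298, adjusted p = 0.00251 in limma) that turned to -0.11 after TMM scaling. EIF2S1, encoding eIF2α, fell 1.76-fold, from 36.1 ± 1.37 to 20.5 ± 0.521 FPKM. Among the 16 eIF2α kinases, phosphatases and eIF2B subunits, 8 rose and 5 fell, also adjusted over the list alone. EIF2AK3, encoding the endoplasmic reticulum kinase PERK, rose 4.27-fold, whereas the eIF2B subunit genes EIF2B1 and EIF2B3 fell 2.52-fold and 2.54-fold. The list as a whole was not called (camera adjusted p = 0.913), its median and mean log2 fold changes differed in sign (0.09 and -0.04), and its median turned to -0.14 under TMM and -0.05 under quantile normalization.

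Amino acid supply genes were mostly higher. Of 17 genes for serine, glycine, one-carbon and asparagine synthesis, 13 rose and 3 fell, with the same numbers adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, rose 20.5-fold, asparagine synthetase ASNS 7.82-fold, from 26.2 ± 0.892 to 205 ± 6.29 FPKM, and the mitochondrial folate enzyme gene ALDH1L2 went from 0.421 to 18.3 FPKM. CAD, the multifunctional enzyme of pyrimidine synthesis, fell from 43.2 to 26.9 FPKM. The list's median log2 fold change was 1.23 (camera adjusted p = 0.0137, and adjusted p = 0.257 with an estimated correlation). Of 13 amino acid transporters, 11 rose over all genes and 12 when adjusted over the list alone, and none fell, with a median of 1.04 (camera adjusted p = 0.00037, and adjusted p = 0.166 with an estimated correlation). The cystine transporter subunit SLC7A11 rose 15.4-fold, SLC1A4 6.48-fold, SLC3A2 3.22-fold and SLC7A5 2.55-fold. Cytosolic aminoacyl-tRNA synthetases split, with 14 of 21 higher and 7 lower over all genes and adjusted over the list alone, and the list was not called (median 0.32, camera adjusted p = 0.175). WARS1, GARS1 and AARS1 rose 6.28-fold, 2.81-fold and 2.87-fold, whereas VARS1 fell 2.08-fold.

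Endoplasmic reticulum stress genes and cytosolic chaperone genes went in opposite directions. All 23 genes of the endoplasmic reticulum list, which holds chaperones, folding enzymes, sensors and transport and degradation genes, many of which the IRE1 and ATF6 branches of the unfolded protein response are known to induce, were higher, over all genes and adjusted over the list alone, with a median log2 fold change of 1.21 (camera adjusted p = 2.71e-07, and adjusted p = 0.153 with an estimated correlation). HSPA5, encoding the lumenal chaperone BiP, went from 139 ± 5.61 to 679 ± 10.5 FPKM (SD, n = 3), SEC24D, a coat protein of export vesicles, rose 11.4-fold, EDEM1 6.85-fold and HYOU1 3.67-fold. In the cytosolic heat shock list, 13 of 14 genes fell and none rose, also adjusted over the list alone, with a median of -1.12 (camera adjusted p = 1.02e-05, and adjusted p = 0.257 with an estimated correlation). The co-chaperone gene FKBP4 fell 4.65-fold, HSP90AA1 2.76-fold, HSPA8 2.32-fold and HSP90AB1 1.89-fold. The summed FPKM of the near-identical copies HSPA1A and HSPA1B, whose reads cannot be divided with certainty, went from 385 ± 37.1 to 233 ± 2.97. Of 16 mitochondrial chaperones and proteases, 12 fell and 3 rose, also adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0229, and adjusted p = 0.361 with an estimated correlation). HSPE1 fell 3.81-fold, HSPD1 1.96-fold and TIMM23 2.00-fold, whereas the protease gene LONP1 rose 1.77-fold. This list's call was lost under quantile normalization (adjusted p = 0.229) and with a mean of at least 5 FPKM (adjusted p = 0.0797).

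Respiratory chain genes of both genomes were lower. Of 44 nuclear-encoded subunits, 41 fell and 1 rose (2 adjusted over the list alone), with a median log2 fold change of -0.49 (camera adjusted p = 3.67e-08, and adjusted p = 0.166 with an estimated correlation). The ATP synthase subunit genes ATP5MC1 and ATP5MC3 fell 2.39-fold and 2.27-fold, and SDHB of complex II fell 1.79-fold. NDUFB5 of complex I, the member that rose, did so 1.26-fold, a call lost after TMM scaling (adjusted p = 0.101). All 13 mitochondrially encoded subunits fell, also adjusted over the list alone, with a median of -0.79 (camera adjusted p = 6.4e-05, and adjusted p = 0.317 with an estimated correlation). ND2 fell 2.01-fold, ND1 1.85-fold and COX1 1.72-fold. COX3, the highest gene in every library, went from 13034 to 7582 FPKM, 1.72-fold, a difference that quantile normalization sets to 0.

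Erythroid genes fell. The fetal globin genes HBG1 and HBG2 went from 3349 ± 44.1 to 1312 ± 34.3 FPKM and from 4386 ± 85.2 to 1885 ± 54.4 FPKM (SD, n = 3), and embryonic HBZ from 556 ± 15.5 to 159 ± 12.2 FPKM. HBA1 fell 4.49-fold and HBA2 4.43-fold. Because HBA1 and HBA2, and likewise HBG1 and HBG2, are near-identical, their summed values are safer: 2320 ± 47.6 against 521 ± 38.2 FPKM for alpha and 7736 ± 113 against 3197 ± 85.2 FPKM for gamma globin. All 9 measured members of the globin list fell, also adjusted over the list alone, with a median log2 fold change of -1.80 (camera adjusted p = 8.12e-05, and adjusted p = 0.257 with an estimated correlation). Of 24 erythroid regulators and membrane proteins, 18 fell and 1 rose, over all genes and adjusted over the list alone, with a median of -0.55 (camera adjusted p = 0.000169, and adjusted p = 0.257 with an estimated correlation). GATA1, the master erythroid regulator, went from 141 ± 0.922 to 73.1 ± 0.123 FPKM, NFE2 fell 5.59-fold and the spectrin gene SPTB 6.17-fold, whereas the membrane skeleton gene EPB41 rose 1.62-fold.

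Heme and iron genes were mixed. Of 15 heme synthesis genes, 9 fell and 4 rose, also adjusted over the list alone, and the list was not called (median -0.19, camera adjusted p = 0.0758). CPOX fell 1.91-fold and FECH 1.65-fold, whereas ALAD rose 1.44-fold. Among 14 iron genes, 5 rose and 9 fell, also adjusted over the list alone (median -0.16, camera adjusted p = 0.284). The ferritin subunit genes FTH1 and FTL rose 3.47-fold and 2.76-fold, to 3109 and 5985 FPKM, whereas transferrin receptor 2 gene TFR2 fell 2.59-fold and the ferrireductase gene STEAP3 3.58-fold. FTL also belongs to the NRF2 target list, in which 14 of 15 genes rose and 1 fell, also adjusted over the list alone, with a median of 1.00 (camera adjusted p = 0.000914, and adjusted p = 0.257 with an estimated correlation). OSGIN1 rose 22.6-fold and AKR1C1, which has near-identical relatives, 4.96-fold, and the peroxiredoxin gene PRDX1 fell 1.32-fold. HMOX1, encoding heme oxygenase 1, was listed at 0 in all vehicle libraries and at 0.00725 ± 0.0126 FPKM in HR-19011.

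Ribosome biogenesis genes fell throughout, while ribosomal protein genes moved little. All 23 genes of the ribosome biogenesis and MYC list were lower, over all genes and adjusted over the list alone, with a median log2 fold change of -1.36 (camera adjusted p = 2.66e-09, and adjusted p = 0.166 with an estimated correlation). The nucleolar factor genes NOP16, UTP20, RRP9 and MRTO4 fell 5.47-fold, 5.05-fold, 4.05-fold and 3.86-fold. Of 46 cytosolic ribosomal protein genes, 27 rose and 6 fell, also adjusted over the list alone, with a median of 0.11 that turned to -0.13 after TMM scaling (camera adjusted p = 0.145). RPL12, RPLP0 and RPS18 rose 1.47-fold, 1.39-fold and 1.35-fold, and RPL35 fell 1.30-fold.

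Replication and mitosis genes were mostly lower. Of 26 S-phase genes, 24 fell and none rose, also adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 9.6e-08, and adjusted p = 0.166 with an estimated correlation). UNG, a uracil glycosylase, fell 3.82-fold, thymidylate synthase TYMS 2.53-fold, and the helicase subunit genes MCM4 and MCM6 2.54-fold and 2.23-fold. Of 24 genes for G2/M and mitosis, 19 fell and 2 rose, also adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.000212, and adjusted p = 0.317 with an estimated correlation). The cyclin genes CCNB1 and CCNA2 fell 1.92-fold and 1.83-fold and BIRC5 1.69-fold, whereas the phosphatase gene CDC25C rose 2.07-fold. Among 13 replication-dependent histone genes, 9 fell and 1 rose, also adjusted over the list alone, with a median of -0.67 (camera adjusted p = 0.00802, and adjusted p = 0.317 with an estimated correlation). H2BC4 fell 2.77-fold, H2BC12 1.97-fold and H1-2 1.79-fold, and H4C8 rose 2.28-fold, within a family of closely similar genes. These histone values come from polyadenylated RNA, so they are not taken as levels of all histone transcripts. Of 12 cell cycle inhibitors and D cyclins, 8 rose and 3 fell, also adjusted over the list alone, without a call for the list (median 0.57, camera adjusted p = 0.143). CDKN1A, encoding the inhibitor p21, rose 12.7-fold, GADD45B 6.65-fold and BTG1 2.50-fold, while CDKN2C fell 1.37-fold.

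Apoptosis regulators went both ways. Of 19 measured, 12 rose and 5 fell, also adjusted over the list alone, and the list was not called (median 0.42, camera adjusted p = 0.155). The death receptor gene TNFRSF10B, encoding DR5, rose 10.1-fold, the BH3-only gene BBC3 8.75-fold and the survival gene MCL1 2.44-fold, whereas BCL2L11, encoding BIM, fell 2.47-fold.

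Autophagy and lysosome genes were mostly higher, with 19 of 23 rising and 4 falling, also adjusted over the list alone, and a median log2 fold change of 0.83 (camera adjusted p = 0.00148, and adjusted p = 0.153 with an estimated correlation). WIPI1, a phagophore protein gene, rose 23.9-fold, the autophagy receptor gene SQSTM1 8.46-fold and the cathepsin gene CTSL 8.32-fold, and ATG16L1 fell 1.43-fold. Of 24 cholesterol genes, 14 fell and 6 rose, also adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0221, and adjusted p = 0.237 with an estimated correlation). DHCR7 and INSIG1 fell 2.85-fold and 2.45-fold, and SREBF2, encoding a regulator of the pathway, rose 1.59-fold. The cholesterol call was lost under quantile normalization (adjusted p = 0.0588) and with a mean of at least 5 FPKM (adjusted p = 0.0695). Glycolysis and hypoxia genes went both ways, 8 of 25 rising and 15 falling, also adjusted over the list alone (median -0.58, camera adjusted p = 0.0507). LDHA and PGAM1 fell 3.49-fold and 2.54-fold, whereas PKM rose 2.08-fold and NDRG1 went from 0.187 to 6.45 FPKM.

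Interferon and early response genes were higher in part. Of 19 listed interferon-stimulated genes only 9 passed the filter. All 9 rose, also adjusted over the list alone, with a median log2 fold change of 1.37 (camera adjusted p = 0.00134, and adjusted p = 0.153 with an estimated correlation), a call lost with a mean of at least 5 FPKM (adjusted p = 0.0509). STAT2 went from 6.57 to 24.2 FPKM, IRF7 from 1.15 to 5.46, IRF1 from 1.37 to 5.11 and OAS3 from 0.289 to 2.54, while IFIT1 and MX1 stayed below the 1 FPKM filter. Of 16 immediate early and AP-1 genes, 11 rose and 3 fell (median 0.47, camera adjusted p = 0.0878), led by IER3 at 21.2-fold, KLF6 at 6.22-fold and SPRY4 at 5.45-fold, with FOS 1.53-fold lower. Of 13 genes listed as JAK-STAT targets downstream of BCR-ABL, 9 rose and 3 fell (median 0.27, camera adjusted p = 0.256). ETV5 rose 3.43-fold, BCL6 and PHLDA1 went from 0.357 to 3.45 and from 0.239 to 6.04 FPKM, and the kinase gene PIM2 fell 2.86-fold. This list also holds genes that are not specific to JAK-STAT signalling, such as ETV5 and PHLDA1. Its counts are therefore not read as JAK-STAT activity. Both of these lists had the same counts adjusted over the list alone.

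Markers of other blood and tissue lineages were sparse. Of 7 measured megakaryocyte markers, 4 rose and 3 fell (median 0.50, camera adjusted p = 0.623). The integrin gene ITGB3 went from 0.186 to 4.44 FPKM, GP6 rose 4.01-fold and RUNX1 from 8.39 to 12.6 FPKM, and GP1BB, which overlaps a readthrough gene, fell 4.78-fold. All 4 measured myeloid markers rose (median 0.97, camera adjusted p = 0.0676): the transcription factor gene SPI1 4.51-fold, CD33 2.53-fold, CD68 1.69-fold and LYZ 1.11-fold. LYZ turned to -0.10 on the log2 scale after TMM scaling and missed the threshold without vehicle replicate 2 (adjusted p = 0.0602), without HR-19011 replicate 1 (adjusted p = 0.0719) and without HR-19011 replicate 3 (adjusted p = 0.0621). CD3D was the single lymphoid marker measured, at 7.40 and 11.9 FPKM, a rise of 1.61-fold, and its list was too short to test. Of 3 measured fibroblast and epithelial markers, 2 rose and 1 fell (median 0.31, and -0.07 under quantile normalization, camera adjusted p = 0.709). The keratin gene KRT19 rose 2.48-fold and EPCAM fell 1.60-fold, while PECAM1 went from 1.12 to 1.64 FPKM, a rise whose sign turned under quantile normalization (-0.07) and whose call was lost under TMM (adjusted p = 0.0907). Counts for these lineage lists were the same adjusted over the list alone.

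**Figure D3:**
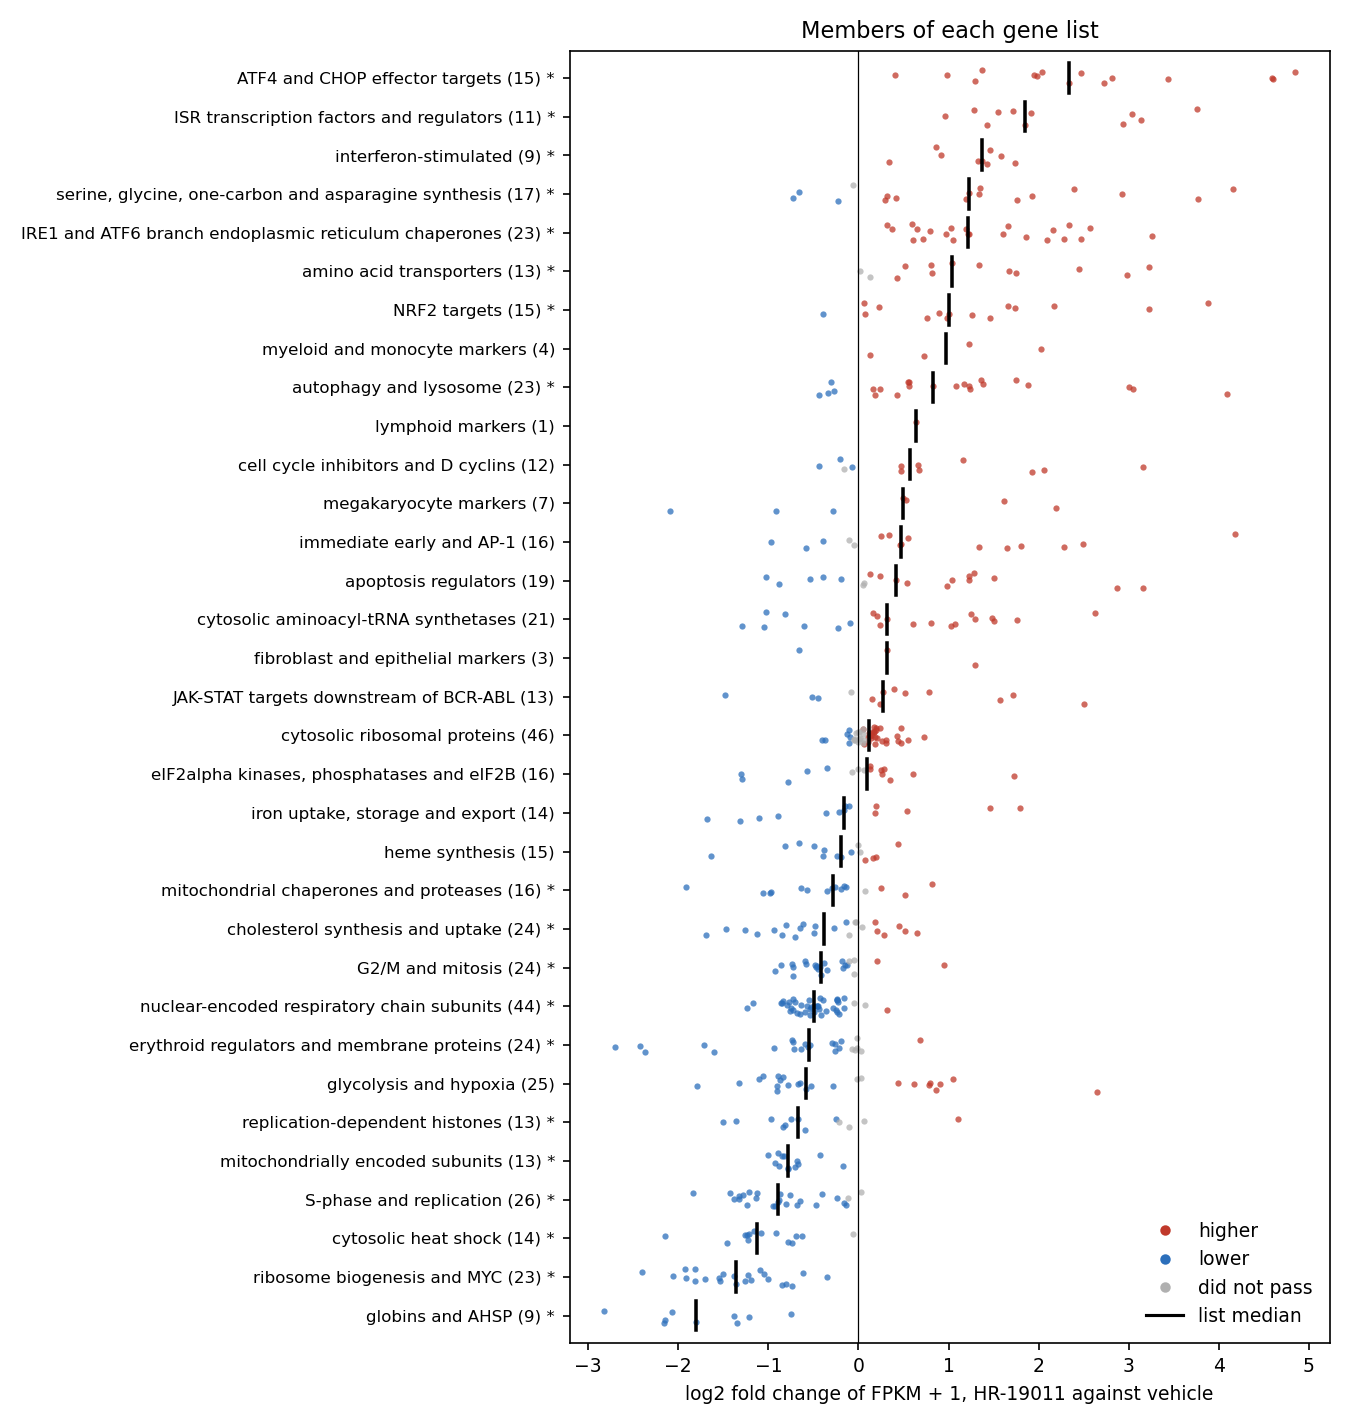
Log2 fold change of FPKM + 1 (HR-19011 against vehicle, horizontal axis) of every measured member of 33 gene lists, with the number measured in parentheses; each dot is a gene, black marks are list medians, and an asterisk marks lists called by camera with its preset correlation. ATF4 and CHOP effector targets have the highest median (2.34) and globins the lowest (-1.80), and the medians of cytosolic ribosomal proteins, of eIF2α kinases with eIF2B, and of fibroblast and epithelial markers change sign under another scaling.

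Across the 33 lists tested, camera called 8 higher and 11 lower with its preset correlation of 0.01, and 0 with an estimated correlation, where the lowest adjusted p was 0.153 and 9 lists had an unadjusted p under 0.05. The estimate rests on 4 residual degrees of freedom, and fry, which asks whether a list's genes move one way without comparing them with other genes, called 18 lists higher and 13 lower. With the preset correlation some lists given above as not called gained a call in other settings. Quantile normalization called 12 lists higher and 9 lower, the higher ones with cytosolic aminoacyl-tRNA synthetases (adjusted p = 0.0135), cytosolic ribosomal proteins (adjusted p = 0.00934), immediate early genes (adjusted p = 0.0244) and myeloid markers (adjusted p = 0.0468) among them. TMM called heme synthesis lower (adjusted p = 0.0227), and TPM called glycolysis and hypoxia lower (adjusted p = 0.0221) and ribosomal proteins higher (adjusted p = 0.00924). With a mean of at least 5 FPKM apoptosis regulators, ribosomal proteins and myeloid markers were called higher (adjusted p = 0.0467, 0.0394 and 0.0452), and without a filter heme synthesis and glycolysis were called lower (adjusted p = 0.00438 and 0.00371) and immediate early genes higher (adjusted p = 0.0259).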

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

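Equal totals without the 100 highest genes and leaving out small nucleolar RNA genes were chosen after seeing the data; the rest were planned. The number of called genes, 10009, ranged from 7050 to 13707 over the alternatives run; leaving out single libraries gave 9686 to 9822 called genes and 2179 to 2206 changed at least 2-fold. Without a filter 8828 genes were higher and 4879 lower. With a mean of at least 5 FPKM 3347 were higher, 847 of these at least 2-fold, and 3703 were lower. Other numbers of genes were tested, but the balance changed as well. Higher genes made up 64.4% of called genes without a filter, 55.0% in the main test and 47.5% at a mean of at least 5 FPKM. A pseudocount of 5, which shrinks low genes by construction, left 992 genes at 2-fold, 581 higher and 411 lower. TMM scaling, which lowered treated values relative to vehicle, gave 1326 genes at least 2-fold lower, and a limma test against 1.5-fold gave 3716 genes, 2201 higher and 1515 lower. TMM turned 173 and quantile normalization 104 of the main calls to the other direction. Of the named genes, EIF2AK1 (-0.11) and LYZ (-0.10) reversed under TMM and PECAM1 (-0.072) under quantile normalization. The other named genes kept their direction in the alternatives run, except that COX3 became 0 under quantile normalization, and 10 values of NDUFB5, PECAM1, COX3 and LYZ, the reversed ones of LYZ and PECAM1 among them, fell short of the threshold. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower, with 9 at an unadjusted p under 0.05, and fry called 31, 18 of them higher. Glycolysis and hypoxia, at adjusted p = 0.0507 in the main test, also passed with either pseudocount, with equal totals without globin and mitochondrial genes or without the 100 highest genes, and without HR-19011 replicate 2. Same-numbered libraries deviated from their group means with correlations of -0.03, -0.0045 and -0.11, so the numbers do not pair them, and no library correlated best with its own number. With the replicate number as a block 5435 genes were higher and 4445 lower. Because depth is unknown, no limit of detection can be given for genes listed at 0.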

Other observations

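The gene families in the first 2 paragraphs were picked by symbol after the values were seen, and the tests of host RNA in small nucleolar RNAs and of background across levels, with genes chosen on 1 vehicle library and in genes listed at 0 were chosen after the result was seen. Mitochondrial ribosomal protein genes fell almost throughout, 71 of 79 lower and 2 higher, with a median log2 fold change of -0.72 (camera adjusted p = 4.47e-14, and adjusted p = 0.123 with an estimated correlation). All 8 subunits of the CCT chaperonin, which folds actin and tubulin, fell (median -0.93), as did 32 of 37 proteasome subunits (2 higher, median -0.49), 20 of 23 nucleoporins (2 higher, median -0.48) and 13 of 17 subunits of RNA polymerases I and III (4 higher, median -0.63). Their camera adjusted p were 0.000219, 1.77e-07, 8.28e-05 and 0.00115, each with adjusted p = 0.216 with an estimated correlation, and these 5 medians kept their sign under each planned scaling.

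Vesicle coat genes went the other way: 17 of 19 COPI and COPII genes rose and none fell, with a median of 0.73 (camera adjusted p = 8.28e-05, and adjusted p = 0.216 with an estimated correlation), while 16 rose and 2 fell under TMM and 16 rose and 1 fell under quantile normalization. COPA went from 35.9 ± 1.13 to 144 ± 2.85 FPKM (SD, n = 3) and SEC23A from 4.97 ± 0.318 to 18.3 ± 0.371. Of 23 lncRNA genes picked by symbol as hosts of small nucleolar RNAs, 17 fell and 5 rose (median -0.55, camera adjusted p = 0.0119, and adjusted p = 0.216 with an estimated correlation), a call lost under quantile normalization (adjusted p = 0.0894). This set does not hold all lncRNA hosts. Over all 80 hosts matched by position, coding or not, 37 fell and 35 rose, with a median of -0.0048. Among the lncRNA hosts that rose, GAS5 went from 199 ± 4.95 to 493 ± 7.16 FPKM and SNHG29 from 370 ± 2.83 to 632 ± 11.7, while SNHG3 fell from 141 ± 1.77 to 45.8 ± 1.72. Of 5 chemokine genes, 4 rose and CCL26 fell (median 2.29, camera adjusted p = 0.121, adjusted p = 0.216 with an estimated correlation, and a call under TMM at adjusted p = 0.0376), with CXCL3 at 2.43 and 19.4 FPKM and CXCL2 at 1.95 and 13.3 FPKM. Of 337 ZNF genes, 201 rose and 71 fell, with a median of 0.24 (camera adjusted p = 0.0119, and adjusted p = 0.216 with an estimated correlation). Under quantile normalization 127 ZNF genes rose and 129 fell, the median was -0.01 and the call was lost (adjusted p = 0.732), and under TMM 149 rose and 116 fell. Vacuolar ATPase genes split, 10 of 18 higher and 6 lower, with a median of 0.17 that turned to -0.06 under TMM (camera adjusted p = 0.637). Of 2 metallothionein genes, MT2A rose and MT1X fell, the latter without a call under TPM. Counts adjusted over the list alone were the same in these families, except 21 nucleoporins lower.

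Small nucleolar RNA genes were listed lower in 149 of 176 cases, 99 of 116 SNORD and 50 of 60 SNORA genes, in polyadenylated RNA and with the division of reads shared with hosts unknown, so these values are not taken as levels of the mature RNAs. The values argue against the planned scalings as the source, since the lowest share called lower over these alternatives was 81.8%. Unless shared reads are divided differently as hosts rise, which was not tested, a lower level of the host RNA cannot account for the 83 small nucleolar RNAs whose host rose: 63 of them were listed lower, with a median log2 fold change of -0.82 (95% interval -1.16 to -0.60), those of GAS5 among them. Lower host transcription stays open, because host RNA also depends on decay: over 167 pairs the small nucleolar RNA value changed by -0.71 relative to its host (95% interval -0.98 to -0.48), an interval that crosses the bound of -0.5 set beforehand, with host matching extended after a narrower match had left this open as well. Loss of short transcripts also cannot be told apart, since 134 other genes spanning under 300 bases had a median of -0.31, with 65 lower and 21 higher. This set includes mitochondrially encoded transcripts, whose share of the summed FPKM fell, microRNA genes and SCARNA genes, so it is not an independent control. Its microRNA genes went both ways, whereas all its genes annotated as snRNA or scRNA were lower. These were RNU6-1 (log2 fold change -0.82), RNU6-2 (-1.38), RNU6-9 (-0.60), RN7SL1 (-0.93) and RN7SL2 (-1.11), looked up after the result was seen and with similar copies elsewhere. A change in the processing or stability of small nucleolar RNAs under HR-19011 was not tested.

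Genes listed above 0 numbered 20068 ± 181 in vehicle and 22228 ± 179 in HR-19011 (SD, n = 3), and 812 genes were at 0 in all vehicle and above 0 in all treated libraries, against 76 the other way. Deeper sequencing would leave FPKM sums equal if no listed 0 were a failed estimate. Genes with a mean under 1 FPKM summed to 1.71 times as much in HR-19011. Because a listed 0 can be a failed estimate and depth is unknown, this does not exclude deeper sequencing. The share freed by mitochondrial and globin transcripts was too small, since the ratio stayed at 1.69 after rescaling without them. A uniform background as the whole source of this sum could not be decided. Of genes under 0.5 FPKM in vehicle, 36.9% were lower. The share was 26.4% to 27.3% with genes chosen on 1 vehicle library and compared with the others, above the bound of 25% set beforehand. But the sum needs a mean rise of only 0.0722 FPKM per gene with a mean under 1 FPKM. With depth unknown, noise could make such genes lower as well. A uniform background would add the same FPKM at every level. Genes at 1 to 2 FPKM in vehicle rose by a median of 0.629 FPKM, 3.50 times the 0.180 of genes at 0.25 to 0.5 FPKM (95% interval 2.83 to 4.22). Genes at 4 to 8 FPKM rose by a median of 0.696, 1.11 times as much as those at 1 to 2. These rises exceed 0.0722 FPKM and so hold other changes, and their ratios cannot test a background of that size. A small background that lifts only genes listed at 0 cannot be told apart either, since genes at 0 in 1 vehicle library rose by a mean of 0.0124 FPKM against the other vehicle libraries and depth is unknown. Broader transcription under HR-19011 stays open beside deeper sequencing and these backgrounds.

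The rise of all 23 genes of the endoplasmic reticulum list, chaperones and others, may be a response to HR-19011 beyond the HRI branch named in the title, or in part within it. Both are hypotheses, since these data hold no protein or kinase measurement. The number called higher was 23 under every planned scaling and 23 whichever library was left out, which argues against these scalings or a single library as the source. The smallest rise in the list, a log2 fold change of 0.31, exceeded the largest shift of the overall median by a planned scaling (-0.21, TMM). All these scalings are relative, so a change in RNA content per cell was not tested. Whether PERK, IRE1 or ATF6 signalling, or ATF4 downstream of HRI, lies behind the rise of the list was not tested.

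Splitting the 6 libraries into 3 and 3 in 10 ways gives too few splits for a share under 0.05. In limma the real split, 1 of the 10, called 10009 genes and 2192 at least 2-fold, and the highest other split called 0 and 0, with 10 to 27 genes at an unadjusted p under 0.05 in the other splits. Every other split mixes libraries of both groups, so the difference between vehicle and HR-19011 adds to its spread. Low counts there follow from this mixing, so the comparison is not read as a test of chance.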
